A study of Bacillus subtilis subsp. subtilis str. 168 with 15 samples.

How the data were processed

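The deposited scanner files hold intensity values made by the authors with Agilent Feature Extraction 11.5.1.1, per the submitters' processing notes: the processed signal is background-subtracted and detrended within each array and not scaled between arrays, per the file headers. The log2 processed signal of each probe had the array's 75th percentile subtracted, outlier spots (1 to 789 per array) were left out, and a feature's value was the median over its probes. The scanner files pair 43735 probes with 5855 features (4230 locus tags, 1571 S-numbered RNA features and 54 other RNAs), with a median of 7 probes per feature. A feature was tested if, on at least 3 arrays, at least 50% of its probes were well above background, which left 5390, of which 1353 were S features. Saturated spots numbered 0.

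All 15 arrays were fitted together by group with limma 3.58.1 in R 4.3.3 (packages jsonlite 2.0.0 and data.table, version 1.17.8), two-sided, and adjusted by the Benjamini-Hochberg method within each of 7 comparisons. The 37 gene lists, the comparisons and the rule for naming genes were fixed before the data were examined. The lists were tested with camera, adjusted over the 37 lists of a comparison, with a preset correlation of 0.01 and again with an estimated one. Of 946 list entries 24 matched no feature. Tested on simulated data with 200 planted changes among 5390 genes, a log2 change of 1 was recovered in 75% to 86% of genes in 6 comparisons and in 46% in the comparison of the tat effects between phases. A log2 change of 0.5 was recovered in 1% to 23%, with 1 to 7 false calls. The comparisons below called a far larger share of features, which loosens the cutoff on the unadjusted p-value. These recovered shares therefore do not carry over to them.

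Named genes followed the rule: the deleted genes and their neighbours, the 10 largest changes each way (5 in the last comparisons, of the tat effects between phases and of the mutants) among genes at least 2-fold changed whose arrays do not overlap between groups, the 3 largest S features each way, all members of lists of 6 or fewer genes, and up to 4 called members of each list. Within that last part the members named were picked after their values were seen. Genes of ICEBs1 outside the 10 largest, named in the closing section, were also chosen after their values were seen.

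The series matrix equals the processed signal (656025 of 656025 values within 1%). Its column medians lie between 51.3 and 56.2 for the tat mutant at lysis and between 264 and 414 on the other arrays. In the authors' gene-level table, scaled to spike-in transcripts per its header, 1437 of 1571 S features (91.5%) were off by more than 0.5 on the log2 scale from the scanner files in most lysis columns, against 30 of 4284 other features. The lysis values of 1121 S features matched another S feature. In the recovery columns 27 S features were off. S features were therefore left out of the alternatives that use this table. The normexp alternative used the median spot signal because the files hold no mean signal. It added an offset of 50 to each value, close to the median processed signal of the tat mutant lysis arrays. The reference table (assembly ASM904v1) served only for names and neighbours, and 602 of 4226 matched locus tags had another symbol there.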

Results

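The series measured RNA of Bacillus subtilis, a Gram-positive soil bacterium, on 15 Agilent 1-colour arrays. Wild-type cells and cells without the Tat genes were sampled at an optical density of 0.9, when the mutant began to lyse, and at an optical density of 2, in the recovery phase. The Tat system exports folded proteins across the cytoplasmic membrane, and the broth held no sodium chloride. A mutant without S313, an RNA feature outside the annotated genes, was sampled in the recovery phase only. Each of the 5 groups held 3 biological replicates according to the series text, and this number of arrays limits the precision. Between 82.6% and 90.3% of the 43735 probes were well above background on the 12 arrays outside the tat mutant's lysis group, and between 74.9% and 79.4% in that group. Correlations between arrays of 1 group, taken across genes, lay between 0.979 and 0.996.

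Arrays of the tat mutant in the lysis phase carried far less signal than the others. The 75th percentile of the probe signal averaged 208 ± 10.7 (SD, n = 3) in the tat mutant at lysis, against 1412 ± 84.3 in the wild type at lysis, 1406 ± 170 and 1080 ± 114 in the wild type and the tat mutant at recovery, and 1125 ± 9.13 in the S313 mutant. Relative to the spike-in transcripts added to every labelling reaction, the 75th percentile of the tat mutant was lower by a log2 difference of -2.85 at lysis, or 7.23-fold (exact two-sided permutation test, p = 0.1, the smallest that 3 against 3 arrays allow). The spike-in level itself differed by 0.09 on the log2 scale (exact permutation test, p = 0.7). All changes below are relative to the 75th percentile of each array unless the spike-in scale is named. In the lysis phase a gene well above background and called higher in the tat mutant therefore took a larger share of a smaller total. Background fell less than the total. Negative controls had medians of 2.16 to 2.57 on tat mutant lysis arrays and 2.96 to 4.97 on wild-type lysis arrays. Features near background can therefore appear higher in the tat mutant at lysis without a rise in RNA. On this log2 scale tatAD, deleted in the mutant, was at -5.23 there and at -6.78 in the wild type.

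**Figure D1:**
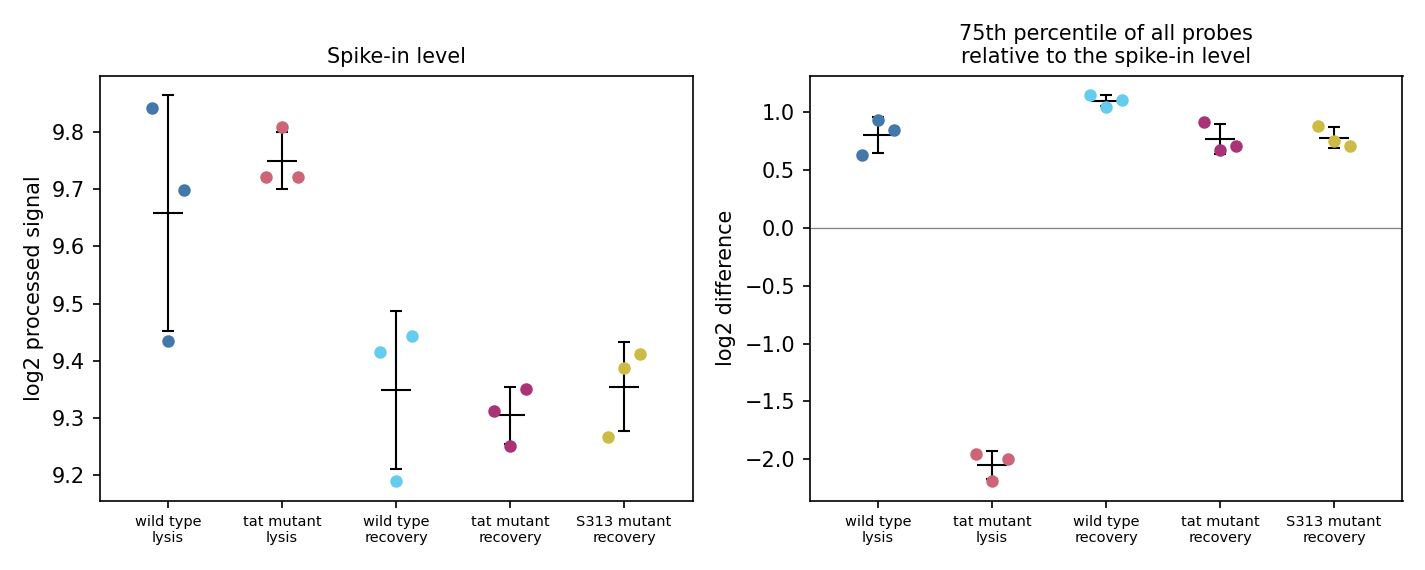
The left panel plots the mean log2 processed signal of the spike-in probes on each array, and the right panel the 75th percentile of all probes minus that level (log2), by group. Points are arrays and bars are mean ± SD (n = 3). The tat mutant lysis arrays average -2.05 in the right panel, and the other 4 groups lie between 0.77 and 1.1.

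The deleted genes were checked first, by signals not scaled between arrays. Signal of tatAY was 5029 ± 717 (SD, n = 3) in the wild type at lysis and 3015 ± 352 at recovery, against 10.4 ± 1.43 and 8.96 ± 0.88 in the tat mutant. For tatCY the wild-type means were 3835 and 2347, and those of the tat mutant 3.46 and 3.05. The other tested Tat gene, tatAC, fell from 543 to 10.2 at lysis, and at recovery its signal was 138 ± 21.8 in the tat mutant against 1050 ± 206 in the wild type. Whether the 2 probes of tatAC lie inside the deleted part is not given in the sources used here. The remaining Tat genes, tatAD and tatCD, were close to background in every group, with means of 3.46 to 13.3 and 2.76 to 14.9, and were not tested. S313 is a 176-nucleotide feature at 972833 to 973008 (suffix c in its feature name; the genome build is not given in the sources used here) with 2 probes. Its signal was 5.95 ± 2.06 in the S313 mutant, where it was not well above background on any array, and 644 ± 185 in the wild type at recovery, at least 24.9-fold higher. That bound compares the mean of the brighter group with the mean, per array of the dimmer group, of the higher of the gene's own value and the lowest signal among probes well above background, and every "at least" below was made the same way. It was made only where no probe of a gene was well above background on any array of a group. Other genes close to background are named below with their fitted values, which give a direction but no exact size or rank. List members of this kind include cotG, epsK and tasA at lysis, epsF and epsG in the tat mutant at recovery, and bhlB in the wild type at lysis.

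S313 was itself higher in the tat mutant than in the wild type at recovery, with a signal of 1413 ± 35.2 and a log2 change of 1.55 ± 0.34 (SE, limma adjusted p = 0.00099). At lysis its change was 1.25 ± 0.34 (adjusted p = 0.0044), which turned to -1.60 on the spike-in scale. Of 7 neighbours of the deleted genes, 6 were well above background on all 15 arrays. In the S313 mutant, yhbF and prkA on either side of S313 rose by 1.20 and 0.91, and in the tat mutant at recovery, where S313 is intact, by 0.95 and 1.29. In the tat mutant at recovery, rex before tatAY rose by 0.95 and pcp after tatCD by 1.04 (0.53 and 1.36 in the S313 mutant), so these rises were not particular to the mutant with the adjacent deletion. In the tat mutant at recovery phoD before tatAD changed by -0.55, while ydiK after tatCY gave 0.32 (adjusted p = 0.091). The remaining neighbour, cotC next to tatAC, was not well above background on any tat mutant array.

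**Figure D2:**
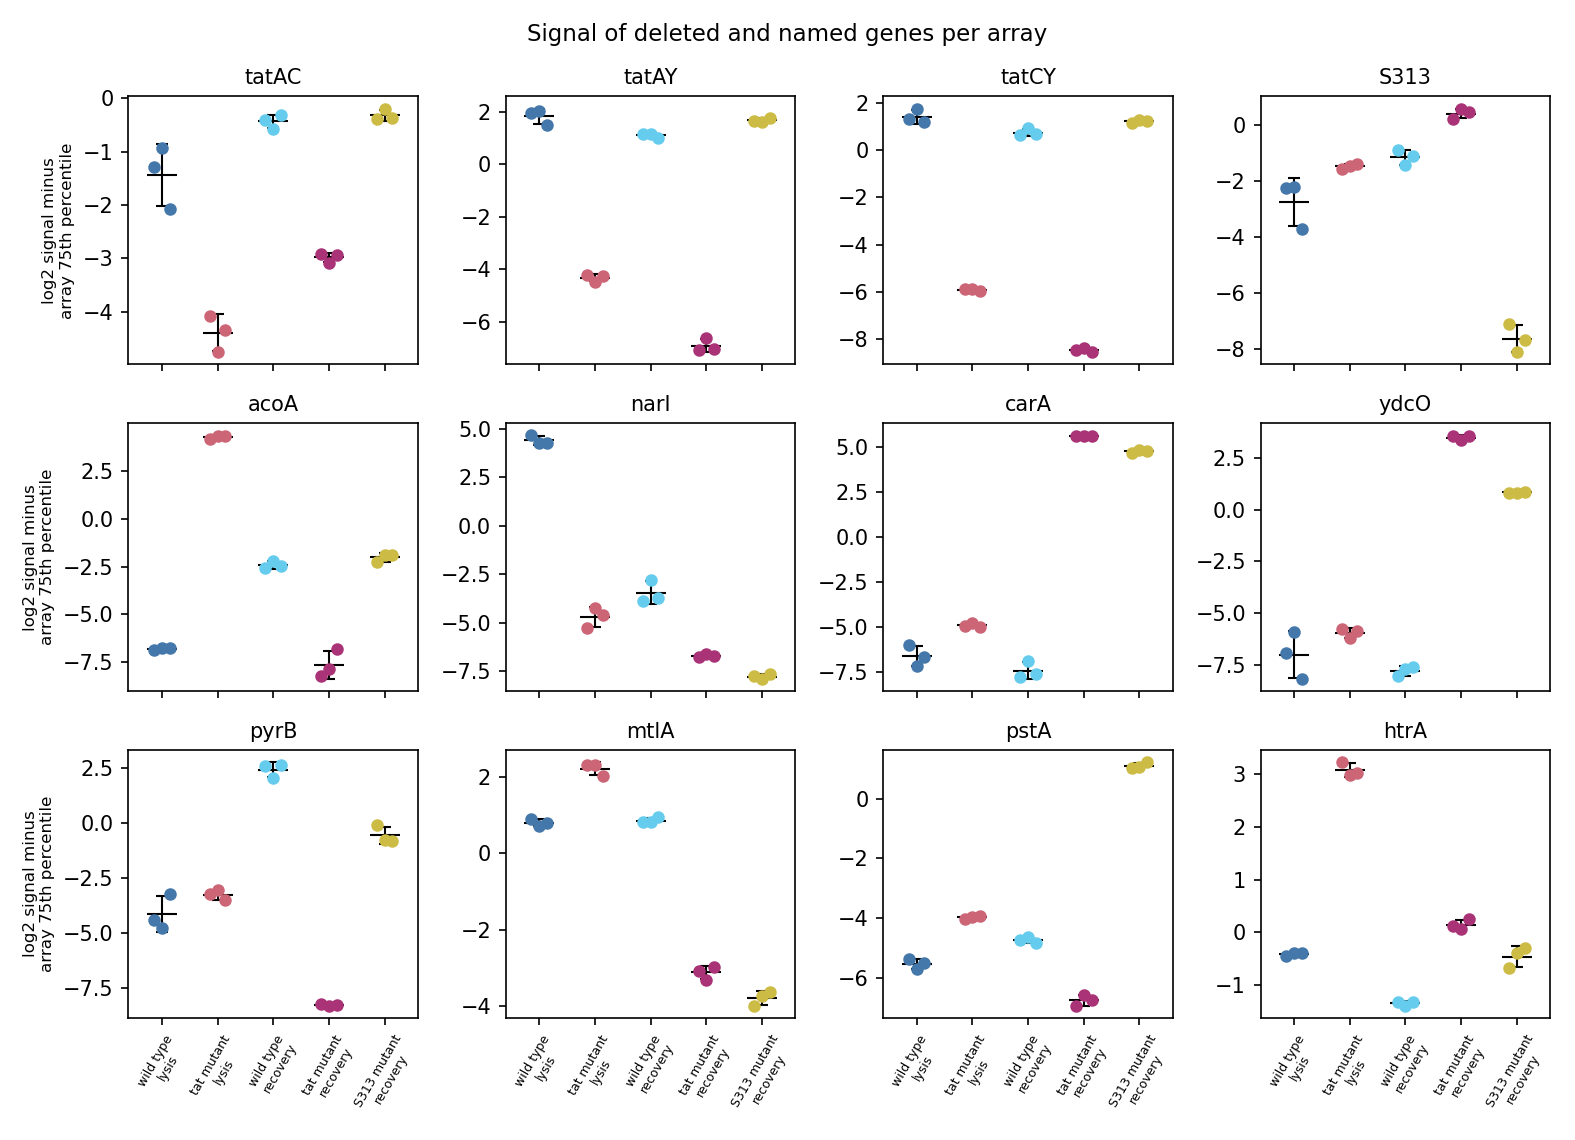
Log2 signal minus the array's 75th percentile for 12 genes, with 1 point per array and bars for mean ± SD (n = 3). tatAY and tatCY are lowest in both tat mutant groups and S313 is lowest in the S313 mutant. acoA is highest in the tat mutant at lysis, and carA and ydcO are highest in both mutants at recovery.

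The comparison of the tat mutant with the wild type at lysis asked what the loss of Tat changed as lysis set in. Genes for the use of acetoin led the increases: acoA and acoB of the acetoin dehydrogenase complex rose by 11.05 ± 0.27 and 10.77 ± 0.14 (log2, SE, n = 3 arrays per group), and acoC and acoL by 8.55 and 8.02. Also among the largest increases were gapB, the gluconeogenic glyceraldehyde-3-phosphate dehydrogenase, by 8.48, the small regulatory RNA sr1 by 8.34 and the catalase gene katA by 7.5. Nitrate respiration genes were among the largest fitted decreases. narI, narH, narJ and narG of nitrate reductase changed by -9.11 ± 0.28, -8.74, -8.60 and -8.35, and narK by -7.40. The cytochrome bd genes cydA, cydB, cydC and cydD changed by -6.66, -7.25, -7.25 and -7.40, and the lactate permease gene lctP by -6.71. Among S-numbered features S534, S342 and S468 rose by 9.56, 7.02 and 6.90. S1447 and S505 fell, with changes of -6.08 and -4.95, and S457 was at least 19.2-fold lower. On 0 of 3 arrays of the lower group at least 50% of the probes of acoA, narI, narG and S534 were well above background. On 1 of 3 those of acoB, narH, narJ and cydA were. These values compare with signals near background. S342 was well above background with any probe on 1 of 3 wild-type arrays.

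In all, 3971 of 5390 tested features passed at an adjusted p of 0.05 (limma, Benjamini-Hochberg), 2412 higher and 1559 lower, and of these 1661 and 840 changed at least 2-fold. The median over all tested features was 0.29. The direction of the split depended on the scaling. The higher share was 60.7% here, 83.0% after normexp background correction, 44.0% after quantile normalization, 3.81% in the authors' deposited gene-level table, 3.84% in the series matrix and 3.68% on the spike-in scale.

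Of 37 gene lists fixed before the data were examined, 16 shifted against all other genes at lysis (camera with a preset correlation of 0.01), and none of the 16 kept its call with an estimated correlation. The SigB general stress list rose in 64 of 66 members, with a median of 3.62 (camera adjusted p = 1.0e-17, adjusted p = 0.11 with an estimated correlation), and its examples nhaX, ydaS, yflT and ohrB rose by 7.65, 7.22, 7.09 and 6.86. CssRS secretion stress genes rose in 4 of 4 (adjusted p = 0.0034, adjusted p = 0.49 with an estimated correlation): the membrane-anchored quality control proteases htrA and htrB by 3.51 and 3.38, and the regulators cssR and cssS by 3.10 and 2.81. Catabolism of arginine, ornithine and histidine had 13 of 14 higher and 1 lower (adjusted p = 5.6e-05, adjusted p = 0.55 with an estimated correlation), with rocA, rocB and rocF up by 6.09, 5.92 and 4.85. On the spike-in scale the medians of these 3 lists stayed above 0, at 0.77, 0.39 and 0.21, although cssS was at -0.043. The CcpA-repressed carbon use list had 34 of 41 higher and 2 lower (adjusted p = 4.9e-06, adjusted p = 0.60 with an estimated correlation), but its median turned from 1.37 to -1.49 on the spike-in scale. Early sporulation had 27 of 28 higher and 1 lower (adjusted p = 0.00045, adjusted p = 0.51 with an estimated correlation) and late sporulation 20 of 22 higher and 1 lower (adjusted p = 0.0021, adjusted p = 0.27 with an estimated correlation). The medians of those sporulation lists, 1.63 and 1.72, also turned on the spike-in scale, to -1.23 and -1.13. sspB and cotG rose by 5.52 and 3.55, and spoVR by 2.79, which became -0.067 on the spike-in scale. Features near background can appear higher in the tat mutant at lysis without a rise in RNA. The deleted gene tatAD was at -6.78 in the wild type and at -5.23 in the tat mutant. Weakly expressed members such as cotG, with a mean signal of 9.5 in the wild type, may share that shift. Whether it accounts for the counts and medians of the sporulation lists was not tested.

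All 21 low-oxygen and fermentation genes fell at lysis, with a median of -6.46 (adjusted p = 2.7e-11, adjusted p = 0.24 with an estimated correlation). PBSX prophage genes fell in 30 of 32 (median -3.65, adjusted p = 1.1e-17, adjusted p = 0.11 with an estimated correlation), xkdN, xkdX and xhlA by -4.75, -4.45 and -4.41. Glycolysis fell in 11 of 13 (adjusted p = 0.0003, adjusted p = 0.60 with an estimated correlation), including ptsI (-2.43) and gapA (-1.84). The peptidoglycan and wall precursor list had 19 of 35 lower and 5 higher (adjusted p = 0.00054, adjusted p = 0.53 with an estimated correlation), with tagF and murD at -2.48 and -2.13. Aerobic respiratory chain genes were lower in 15 of 22 and higher in 4 (adjusted p = 0.0028, adjusted p = 0.61 with an estimated correlation), ctaC by -1.54. In the Sec secretion list 14 of 21 were lower and 4 higher (adjusted p = 0.0034, adjusted p = 0.12 with an estimated correlation), and its most changed members bdbB and bdbA, at -4.17 and -3.36, belong to the SPbeta prophage. Branched-chain amino acid and CodY targets had 10 of 16 lower and 6 higher (adjusted p = 0.0051, adjusted p = 0.60 with an estimated correlation), leuC and leuB at -4.79 and -4.66. The SigM and SigX list had 16 of 31 lower and 6 higher (adjusted p = 0.02, adjusted p = 0.51 with an estimated correlation), and sulfur and cysteine 10 of 20 lower and 4 higher (adjusted p = 0.02, adjusted p = 0.64 with an estimated correlation). Biofilm matrix genes were lower in 13 of 21 and higher in 3 (adjusted p = 0.0038, adjusted p = 0.60 with an estimated correlation), but the shift of the list turned to 0.53 after normexp correction and to 0.64 among genes detected on all 15 arrays. Within it epsK and tasA, at -2.31 and -2.27, turned to 1.60 and 1.12 after normexp correction, and bslA, up by 2.23, turned to -0.62 on the spike-in scale.

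The other 21 lists did not pass at lysis. The list of Tat substrates and partners gave adjusted p = 0.70: phoD was at 1.42 and wprA at -1.92, which passed, and qcrA, efeB and ykuE at 0.54, -0.02 and -0.06 did not. On the spike-in scale phoD turned to -1.43 and qcrA to -2.31, and after normexp correction ykuE turned to 1.91. In the LiaRS operon liaH and liaI passed at 2.83 and 2.78, liaS and liaR at -0.42 and -0.72, and liaG and liaF did not, at 0.36 and -0.10 (list adjusted p = 0.86). On the spike-in scale liaH, liaI and liaG were at -0.019, -0.071 and -2.49, and after normexp correction liaR, liaS and liaF turned to 0.48, 0.38 and 1.11. The Fur list had 16 of 27 members higher and 3 lower (adjusted p = 0.13), feuA by 3.31, and its shift turned to -1.21 after normexp correction. The TCA cycle list had 9 of 13 higher and 1 lower (adjusted p = 0.18), odhB by 1.46, or -1.39 on the spike-in scale, and its shift turned to -1.43 after normexp correction. The SOS list (adjusted p = 0.68), heat shock chaperones (0.68, with a shift of -1.25 after normexp correction), autolysins (0.63), osmolyte uptake (0.98), motility (0.13) and ribosomal proteins (0.64) did not pass either. Adjusted over the list alone, the higher and lower counts of the 16 passing lists were the same except for PBSX, with 31 lower, and the respiratory chain, with 5 higher. In 0 passing lists of any comparison did the median and the mean shift differ in sign.

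All 3 tat mutant lysis arrays shared 1 slide with 1 of the wild-type arrays. With the slide as a block, and within that slide, acoA was at 11.14 and narI at -9.36. The other wild-type lysis arrays shared no slide with a tat mutant array. Both fits therefore compare with the same single wild-type array and give 1 estimate. At recovery too 1 wild-type array shared a slide with the mutants, so slide-blocked changes against the wild type rest on that array. In the fit within that slide and every later fit within slides at least 1 group had a single array. It was assumed to vary like the arrays of the other groups, so counts from such fits rest on the spread of those groups. With the block and within the slide the SigB list's mean shift at lysis was 3.13, against 3.17 without the block. The low-oxygen list's was -5.52, against -5.74.

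At recovery the tat mutant had very high arginine synthesis RNA and very low pyrimidine synthesis RNA. carA and carB, the arginine-specific carbamoyl phosphate synthetase, rose by 13.03 ± 0.25 and 12.17 (log2, SE, n = 3 arrays per group), argD by 11.57 and argF by 10.67. A run of genes of the integrative element ICEBs1 rose by similar amounts: ydcT by 11.32, ydcO by 11.24, ydcQ by 10.87 and conB by 10.58, with conC at least 674-fold and the relaxase gene nicK at least 439-fold higher. Of the pyrimidine genes, pyrB was at least 412-fold lower, and pyrC, pyrAA, pyrP, pyrAB, pyrD, pyrK and pyrE changed by -10.04, -9.86, -7.12, -6.80, -6.22, -6.01 and -5.82. The pyrroline-5-carboxylate dehydrogenase gene rocA changed by -6.95 ± 0.12 and the glycerol-3-phosphate permease gene glpT by -6.17. S172 rose by 11.26, S171 was at least 724-fold and S1118 at least 158-fold higher, and S801, S1460 and S1551 changed by -6.66, -6.41 and -5.67. Several of these were near background in the lower group. At least 50% of the probes were well above it on 0 of 3 arrays for carA, ydcT, ydcO, ydcQ, conB, pyrAA, S172 and S801. For carB, argD and pyrC they were on 1 of 3. With any probe, carA and S172 were well above background on 2 of 3 wild-type arrays and ydcT on 1 of 3.

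Here 3934 features passed, 1971 higher and 1963 lower, with 1195 and 1126 changed at least 2-fold. The higher share of 50.1% became 31.7% in the authors' gene-level table, 34.9% in the series matrix and 36.3% on the spike-in scale. The count fell to 2284 after normexp correction. Of the 37 lists 24 passed, none with an estimated correlation. On the spike-in scale all 24 medians kept their direction.

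The arginine synthesis list rose in 9 of 9, with a median of 10.18 (adjusted p = 6.8e-09, adjusted p = 0.13 with an estimated correlation). Antimicrobial peptide and secondary metabolite genes were higher in 33 of 51 and lower in 8 (adjusted p = 7.8e-06, adjusted p = 0.41 with an estimated correlation), led by the subtilosin genes sboA, sboX, albG and albF at 8.64, 8.28, 7.04 and 6.96. Iron uptake genes of the Fur list were higher in 20 of 27 and lower in 3 (adjusted p = 2.3e-05, adjusted p = 0.24 with an estimated correlation), fbpB by 4.76 and the bacillibactin synthesis gene dhbF by 3.92. The TnrA and nitrogen list had 12 of 14 higher and 1 lower (adjusted p = 0.00046, adjusted p = 0.39 with an estimated correlation), with the urease genes ureB and ureA up by 4.48 and 4.29. SigW genes were higher in 41 of 52 and lower in 2 (adjusted p = 1.4e-06, adjusted p = 0.41 with an estimated correlation), yuaI by 3.09 and floT by 2.88. LiaRS genes rose in 6 of 6 (adjusted p = 0.0013, adjusted p = 0.13 with an estimated correlation): liaI and liaH by 4.12 and 3.89, liaG, liaF, liaS and liaR by 1.62, 1.45, 1.21 and 1.02. CssRS genes rose in 4 of 4 (adjusted p = 0.015, adjusted p = 0.41 with an estimated correlation), htrA, htrB, cssR and cssS by 1.5, 1.06, 0.94 and 0.88. Extracellular proteases were higher in 6 of 8 and lower in 1 (adjusted p = 0.02, adjusted p = 0.41 with an estimated correlation), with aprE, subtilisin, up by 3.66 and vpr by 2.29. Branched-chain amino acid and CodY targets had 8 of 16 higher and 2 lower (adjusted p = 0.019, adjusted p = 0.45 with an estimated correlation), with dppD of the dipeptide permease at 3.75.

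Early sporulation had 16 of 28 higher and 5 lower (adjusted p = 0.015, adjusted p = 0.41 with an estimated correlation), and the aerobic respiratory chain 13 of 22 higher and 3 lower (adjusted p = 0.047, adjusted p = 0.58 with an estimated correlation), with the cytochrome c oxidase genes ctaF and ctaC up by 2.86 and 2.80.

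Pyrimidine synthesis fell in 10 of 10 (median -6.51, adjusted p = 1.6e-06, adjusted p = 0.24 with an estimated correlation) and purine synthesis in 19 of 19 (median -3.17, adjusted p = 9.0e-10, adjusted p = 0.24 with an estimated correlation), with purA, pbuO and pbuX at -5.16, -4.80 and -3.98. Ribosomal protein genes fell in 49 of 51 (median -2.47, adjusted p = 1.3e-13, adjusted p = 0.33 with an estimated correlation), including rplF (-2.90) and rpsH (-2.89). Biofilm matrix genes fell in 20 of 21 and 1 rose (median -2.89, adjusted p = 1.0e-07, adjusted p = 0.24 with an estimated correlation), epsF and epsG by -4.81 and -4.66. Both prophages were lower: PBSX in 29 of 32 with 2 higher (adjusted p = 9.0e-10, adjusted p = 0.24 with an estimated correlation) and SPbeta in 24 of 35 with 6 higher (adjusted p = 0.00011, adjusted p = 0.41 with an estimated correlation), with xkdQ, xlyA, yonJ and yonN at -2.97, -2.94, -4.62 and -4.47. The SigB list, raised at lysis, now had 42 of 66 lower and 14 higher (median -0.80, adjusted p = 0.0043, adjusted p = 0.41 with an estimated correlation).

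Motility and chemotaxis genes were lower in 36 of 54 and higher in 7 (adjusted p = 0.00059, adjusted p = 0.45 with an estimated correlation), glycolysis in 12 of 13 (adjusted p = 0.00053, adjusted p = 0.41 with an estimated correlation), and the TCA cycle in 10 of 13 with 2 higher (adjusted p = 0.014, adjusted p = 0.44 with an estimated correlation), odhA by -2.22. The Pho list was lower in 13 of 18 and higher in 1 (adjusted p = 0.0084, adjusted p = 0.39 with an estimated correlation), with glpQ at -4.81. Wall precursor synthesis was lower in 22 of 35 and higher in 4 (adjusted p = 0.0095, adjusted p = 0.41 with an estimated correlation), murD by -3.02, and the SigM and SigX list in 18 of 31 with 7 higher (adjusted p = 0.047, adjusted p = 0.41 with an estimated correlation). Adjusted over the list alone, the counts of these 24 lists were the same except for the proteases, with 2 lower, and the CodY targets, with 1 lower.

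Among lists that did not pass, catabolism of arginine, ornithine and histidine had members going both ways (6 higher and 7 lower of 14, adjusted p = 0.65): the histidine gene hutM rose by 6.18, and rocG and rocD, of glutamate and ornithine breakdown, changed by -5.80 and -5.72. The Tat substrates and partners had ykuE and qcrA up by 1.77 and 1.18, phoD at -0.55, and efeB and wprA at 0.07 and -0.31, which did not pass (list adjusted p = 0.65). PerR and oxidative stress gave adjusted p = 0.077, competence 0.079, late sporulation 0.054, sulfur and cysteine 0.41, osmolyte uptake 0.22 and the SOS list 0.80. With the slide as a block 22 of the 24 lists still passed, and 21 within the slide described next. Within the slide that held 1 wild-type and 1 tat mutant array, with the spread taken from the other groups, 2343 features passed, with carA at 12.49 and the fitted change of pyrB at -10.28, and with the slide as a block 3114 did. Arginine synthesis shifted by 10.40 without the block, 10.16 with it and 10.10 within the slide. The corresponding values of pyrimidine synthesis were -7.17, -7.62 and -7.52.

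The S313 mutant at recovery had raised arginine synthesis RNA too. carA, carB, argD, argF, argB and argJ rose by 12.17 ± 0.25, 11.32, 10.74, 9.84, 9.43 and 8.81 (log2, SE for carA, n = 3 arrays per group), and ydcO, ydcT and ydcQ by 8.61, 8.56 and 8.28, with conC at least 92.5-fold higher. The decreases were smaller. Genes of mannitol uptake and use, mtlA, mtlF and mtlD, changed by -4.64 ± 0.13, -4.60 and -4.58, narI and narG by -4.31 and -3.42, and the purine transporter gene pbuO by -4.07. The amino acid transporter gene steT, the uracil salvage gene upp, the GMP reductase gene guaC and glpT changed by -3.93, -3.68, -3.65 and -3.58. S172 rose by 8.47, with S171 at least 122-fold and S1118 at least 54.4-fold higher. S132 and S82 changed by -5.00 and -3.29, and S524 was at least 7.80-fold lower. The wild-type arrays near background for carA, carB, argD, ydcO, ydcT, ydcQ and S172 are those of the tat comparison, so these sizes are fitted values too. In the S313 mutant narI and narG had at least 50% of their probes well above background on 0 of 3 arrays, and S132 on 1 of 3.

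A total of 3504 features passed, 1552 higher and 1952 lower, with 890 and 903 changed at least 2-fold, around an all-gene median of -0.11. The higher share was 44.3%, against 26.2% in the authors' gene-level table, 29.8% in the series matrix and 29.5% on the spike-in scale. The count fell to 1634 after normexp correction. The list test passed 20 lists, none with an estimated correlation, and none of their medians changed direction on the spike-in scale.

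SigW genes, a cell envelope stress regulon, rose in 50 of 52, with a median of 3.32 (adjusted p = 1.0e-27, adjusted p = 0.14 with an estimated correlation): yuaF, yuaI and the flotillin gene floT by 5.92, 5.83 and 5.73, and the fosfomycin resistance gene fosB by 5.20. Arginine synthesis rose in 9 of 9 (median 9.43, adjusted p = 1.3e-10, adjusted p = 0.14 with an estimated correlation). In the Fur list 19 of 27 were higher and 6 lower (adjusted p = 1.6e-05, adjusted p = 0.25 with an estimated correlation), dhbF by 4.74 and dhbA by 3.81. Antimicrobial peptide genes were higher in 32 of 51 and lower in 6 (adjusted p = 2.0e-06, adjusted p = 0.48 with an estimated correlation), with sdpC, sboA, skfB and skfA up by 3.60, 3.30, 3.25 and 3.18. LiaRS rose in 6 of 6 (adjusted p = 0.0066, adjusted p = 0.14 with an estimated correlation), liaI by 2.47, liaH by 2.29, and liaG, liaF, liaS and liaR by 0.79, 0.63, 0.66 and 0.59. CssRS rose in 4 of 4 (adjusted p = 0.048, adjusted p = 0.50 with an estimated correlation), htrA, htrB, cssR and cssS by 0.89, 0.51, 0.48 and 0.48. The TnrA list had 9 of 14 higher and 1 lower (adjusted p = 0.0075, adjusted p = 0.50 with an estimated correlation), competence 13 of 20 higher and 2 lower (adjusted p = 0.017, adjusted p = 0.50 with an estimated correlation), and proteases 5 of 8 higher and 1 lower (adjusted p = 0.046, adjusted p = 0.50 with an estimated correlation), vpr by 2.53. CcpA-repressed carbon use had 25 of 41 higher and 6 lower (adjusted p = 0.023, adjusted p = 0.64 with an estimated correlation), with iolA at 1.77 and the mtl genes in the opposite direction.

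Purine synthesis fell in 19 of 19 (median -2.26, adjusted p = 8.4e-10, adjusted p = 0.25 with an estimated correlation), purE by -2.89. Ribosomal protein genes fell in 49 of 51 and 1 rose (median -1.21, adjusted p = 8.0e-10, adjusted p = 0.42 with an estimated correlation), rpsD by -1.99 and rpsF by -1.70. PBSX fell in 29 of 32 with 1 higher (adjusted p = 2.5e-09, adjusted p = 0.24 with an estimated correlation), xtmB by -2.04 and xkdJ by -1.99, and the biofilm matrix in 18 of 21 with 1 higher (adjusted p = 4.8e-05, adjusted p = 0.40 with an estimated correlation), epsF by -2.34. Motility was lower in 37 of 54 and higher in 1 (adjusted p = 4.4e-05, adjusted p = 0.51 with an estimated correlation), and wall precursor synthesis in 25 of 35 (adjusted p = 0.00015, adjusted p = 0.40 with an estimated correlation), murD by -1.73. The SigM and SigX list had 22 of 31 lower and 4 higher (adjusted p = 0.0035, adjusted p = 0.29 with an estimated correlation), mreBH at -2.70, SigB 37 of 66 lower and 12 higher (adjusted p = 0.017, adjusted p = 0.59 with an estimated correlation), sulfur and cysteine 13 of 20 lower (adjusted p = 0.038, adjusted p = 0.63 with an estimated correlation), and low-oxygen genes 9 of 21 lower and 1 higher (adjusted p = 0.045, adjusted p = 0.64 with an estimated correlation). The counts of the 20 lists were the same when adjusted over the list alone, except for motility, with 38 lower.

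Some lists that did not pass held large changes. In the Pho list, pstBA, pstBB and pstA of the phosphate transporter rose by 5.96, 5.87 and 5.83 while 8 of 18 members were higher and 8 lower, so that the list had a median of -0.45 and a mean shift of 1.18 (adjusted p = 0.30). In arginine, ornithine and histidine catabolism hutM and hutH rose by 7.01 and 6.55, and 7 of 14 members were higher and 7 lower (adjusted p = 0.53). The dipeptide permease gene dppC rose by 4.08 and ctaD by 2.09. Pyrimidine synthesis had 4 of 10 lower, pyrB by -2.98, and did not pass (adjusted p = 0.17), nor did SPbeta with 8 of 35 lower and 3 higher (adjusted p = 0.48). Of the Tat substrates and partners, efeB, ykuE and qcrA passed at -1.15, 1.12 and 0.93, and phoD and wprA did not, at -0.39 and -0.02 (list adjusted p = 0.92). With the slide as a block 2771 features passed, and 2525 within the slide that held 1 wild-type array, its spread taken from the other groups, and 2 of this mutant. carA was at 11.66 and 11.69 in those fits, and mtlA at -4.53 and -4.49. The SigW shift was 3.22 without the block and 3.10 in both, and that of arginine synthesis 9.53, 9.25 and 9.28. Of the 20 lists 19 still passed with the block and 18 within the slide.

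**Figure D3:**
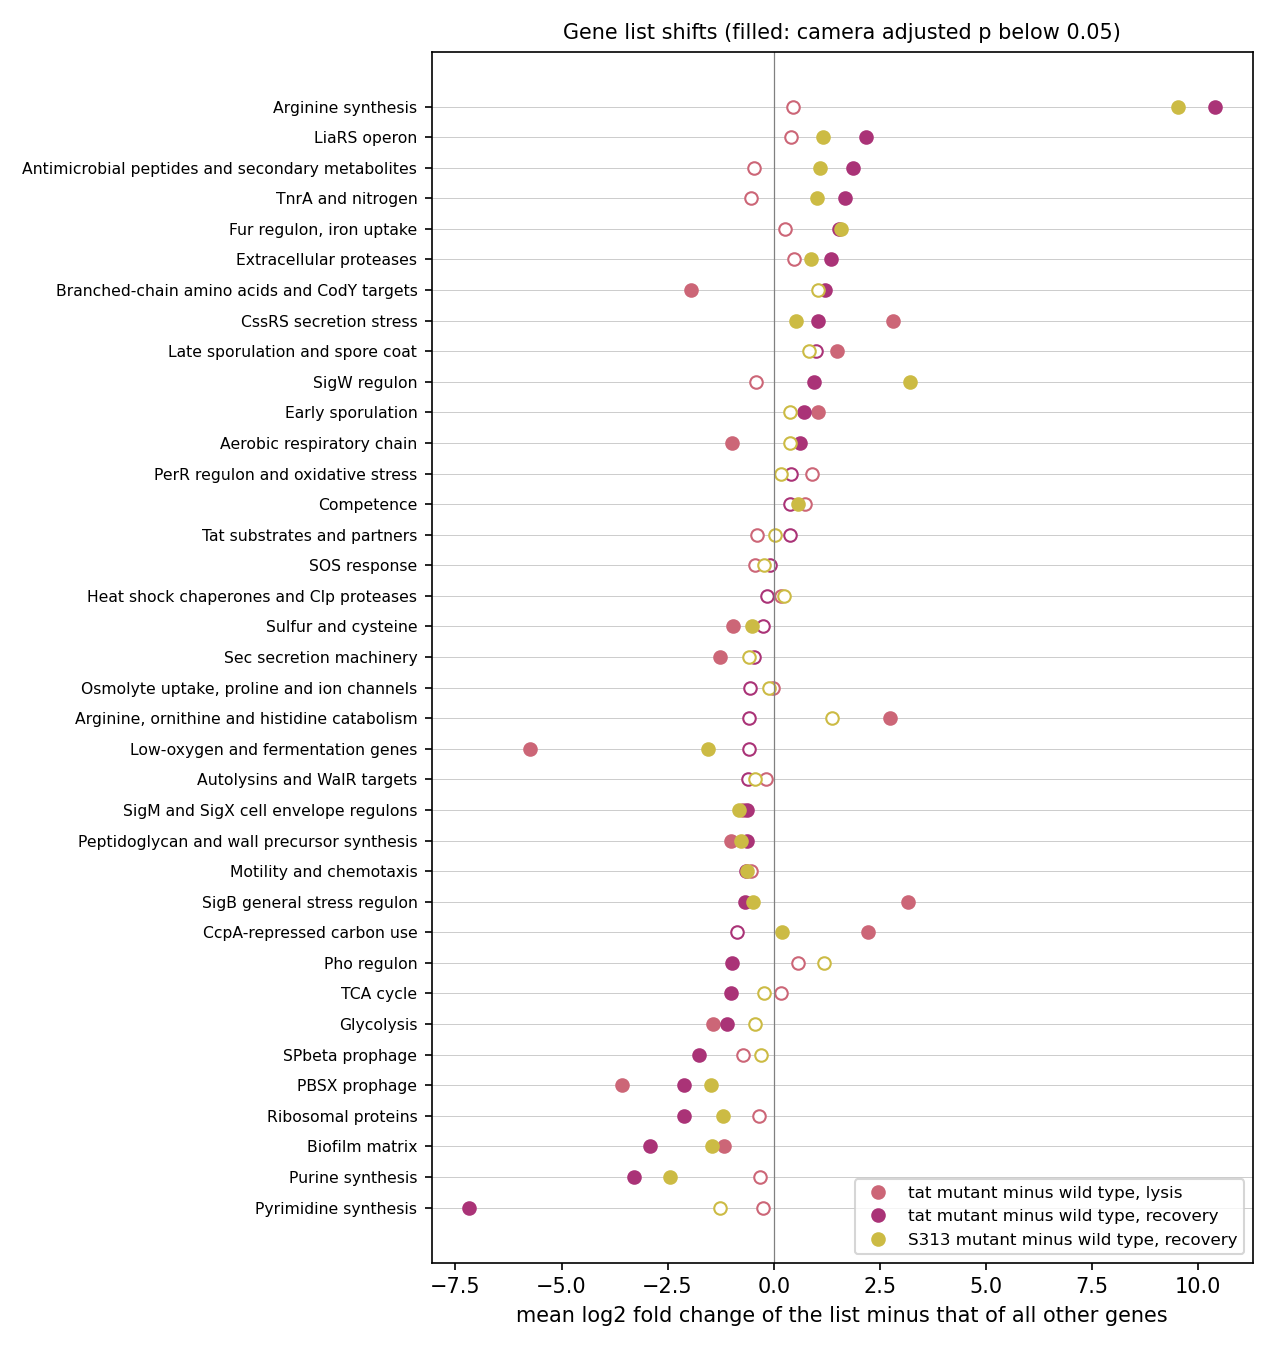
Mean log2 fold change of each of the 37 gene lists minus that of all other genes (horizontal axis) for both tat mutant comparisons and the S313 mutant against the wild type. Filled points passed camera with the preset correlation. Arginine synthesis is at 10.40 and 9.53 in the mutants at recovery, and low-oxygen genes are at -5.74 in the tat mutant at lysis.

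The responses of the mutants at recovery overlapped. Of the features that passed in each, 1285 were higher in both (568 for independent lists of those sizes) and 1547 lower in both (711), and 118 passed in opposite directions. Counting only changes of at least 2-fold, 686 were higher in both (197), 715 lower in both (189) and 12 opposite. Across genes, which are not independent replicates, the log2 changes correlated with r = 0.81, against a mean of 0.50 and a highest value of 0.54 in 100 simulations of unchanged groups set against the same wild-type arrays. The covariance was 2.00, against a simulated mean of 0.025, a difference of 1.97. Simulated groups shared 0 calls, which was fixed in advance because they held no change. The simulations show what noise of the shared wild-type arrays adds to the covariance. They do not show how far large unrelated responses would overlap. Within the slide that held all 3 strains the correlation was 0.80 and the covariance 1.96. The 3 wild-type arrays are common to both responses and are too few to split.

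Tested directly against the tat mutant at recovery, the S313 mutant had higher phosphate transporter and pyrimidine RNA and lower subtilosin RNA. pstA, pstC, pstBB and pstBA were higher by 7.84 ± 0.12 (log2, SE, n = 3 arrays per group), 7.5, 7.45 and 7.21. pyrB was at least 52.3-fold higher, and pyrAA and pyrC were higher by 7.48 and 7.32. The difference was -5.34 ± 0.31 for sboA, -5.15 for sboX, -4.21 for albG, -4.22 for the C4-dicarboxylate transporter gene dctP and -4.06 for yebD. S801 and S118 were higher by 5.59 and 4.88 and S764 at least 6.35-fold, and S1450, S229 and S437 differed by -4.34, -4.09 and -3.92. In the tat mutant pstA, pstC, pyrAA, S801 and acoA had at least 50% of their probes well above background on 0 of 3 arrays. For pstBA, pyrC and acoB it was 1 of 3. Their values are not exact sizes.

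This comparison passed 2610 features, 1304 higher and 1306 lower, with 587 and 452 at least 2-fold apart, around an all-gene median of -0.09. The higher share of 50% became 39.3% with array median scaling, and the count fell to 758 after normexp correction. SigW genes were higher in the S313 mutant in 49 of 52 and lower in 1 (median 2.39, adjusted p = 5.2e-31, adjusted p = 0.12 with an estimated correlation), fosB by 3.78, yuaF by 3.16 and yxzE by 3.09. Pyrimidine synthesis was higher in 10 of 10 (median 6.12, adjusted p = 4.4e-10, adjusted p = 0.12 with an estimated correlation), ribosomal proteins in 40 of 51 (adjusted p = 1.0e-10, adjusted p = 0.35 with an estimated correlation), rplN by 1.66, and arginine, ornithine and histidine catabolism in 14 of 14 (adjusted p = 5.9e-10, adjusted p = 0.33 with an estimated correlation), rocA by 4.22 and rocB by 3.60. Biofilm matrix genes were higher in 19 of 21 and lower in 1 (adjusted p = 1.9e-08, adjusted p = 0.33 with an estimated correlation), epsF by 2.47. SPbeta was higher in 22 of 35 and lower in 2 (adjusted p = 2.7e-07, adjusted p = 0.38 with an estimated correlation), yonF by 3.82 and yonJ by 3.77, and PBSX in 23 of 32 (adjusted p = 2.6e-06, adjusted p = 0.33 with an estimated correlation), xkdT by 1.59.

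Among carbon and energy lists 3 were higher in the S313 mutant than in the tat mutant: CcpA-repressed genes in 26 of 41 with 4 lower (adjusted p = 2.6e-06, adjusted p = 0.48 with an estimated correlation), acoA by 5.61 and acoB by 4.39, the TCA cycle in 13 of 13 (adjusted p = 1.1e-05, adjusted p = 0.33 with an estimated correlation), odhA by 1.38, and glycolysis in 10 of 13 (adjusted p = 0.00053, adjusted p = 0.46 with an estimated correlation), ptsG by 1.71. Purine synthesis was higher in 16 of 19 and lower in 1 (adjusted p = 1.3e-05, adjusted p = 0.35 with an estimated correlation), purA by 2.36. Arginine synthesis was lower in 9 of 9 (median -0.85, adjusted p = 0.0016, adjusted p = 0.33 with an estimated correlation), as were LiaRS in 6 of 6 (adjusted p = 0.0025, adjusted p = 0.12 with an estimated correlation) and CssRS in 4 of 4 (adjusted p = 0.031, adjusted p = 0.45 with an estimated correlation), with liaI, liaH, htrA and htrB at -1.66, -1.60, -0.61 and -0.55. Low-oxygen genes were lower in 12 of 21 (adjusted p = 0.00053, adjusted p = 0.45 with an estimated correlation), fnr by -2.36, the aerobic respiratory chain did not pass (10 lower and 7 higher of 22, adjusted p = 0.27), and the TnrA list was lower in 8 of 14 with 2 higher (adjusted p = 0.023, adjusted p = 0.50 with an estimated correlation), nasD by -2.40. Of the 37 lists 21 passed, none with an estimated correlation. Within the slides that held both mutants, each with a single array of 1 mutant and the spread taken from the other groups, 1353 and 1172 features passed, and 2504 with the slide as a block. pstA was at 8.07, 7.66 and 7.87 and sboA at -5.01, -5.93 and -5.47 in those fits, and the SigW shift of 2.27 was 2.23 in each. Of the 21 lists 18 still passed within 1 of these slides, and all 21 within the other and with the block. When adjusted over the list alone, 9 of the 21 lists had 1 to 3 more called members, SigW 50 higher among them.

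Between the sampling points RNA of proline and arginine breakdown genes rose in the wild type. putB and putC of proline breakdown rose by 8.32 ± 0.16 (log2, SE, n = 3 arrays per group) and 7.82, rocB, rocA, rocC and rocG by 7.48, 7.15, 6.63 and 6.42, pyrB and pyrC by 6.58 and 6.20, sr1 by 6.63 and gapB by 6.03. The trehalose genes treP and treA changed by -9.04 ± 0.15 and -8.66, narK, narI, narJ, narH and narG by -8.05, -7.85, -7.55, -7.40 and -7.17, and cydC, cydD and cydB by -7.92, -7.58 and -7.43. S1460 rose 128-fold, and S1461 and S1551 by 6.12 and 5.83. S1447 and S505 changed by -6.74 and -5.87, and S1448 was at least 15.6-fold lower. No slide held both phases, so slide and phase cannot be told apart in the wild type.

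In this comparison 3584 features passed, 2216 higher and 1368 lower, with 1352 and 562 at least 2-fold, around an all-gene median of 0.22. The higher share of 61.8% became 48.9% with quantile normalization, 43.4% with array median scaling and 77.1% on the spike-in scale. The count fell to 1857 after normexp correction. Of the lists 19 passed. The Fur list fell in 27 of 27, with a median of -2.53, and held with an estimated correlation too (adjusted p = 5.0e-20, adjusted p = 0.025 with an estimated correlation), dhbF by -5.61 and dhbA by -5.07. Low-oxygen genes fell in 21 of 21 (adjusted p = 1.9e-12, adjusted p = 0.19 with an estimated correlation), glycolysis in 13 of 13 (adjusted p = 2.4e-09, adjusted p = 0.26 with an estimated correlation), ptsG by -6.20, gapA by -4.05 and eno by -3.19, and PBSX in 30 of 32 (adjusted p = 1.6e-18, adjusted p = 0.066 with an estimated correlation), xkdN by -3.20. Heat shock chaperones were lower in 11 of 15 and higher in 1 (adjusted p = 0.00011, adjusted p = 0.25 with an estimated correlation), groES by -1.77 and groEL by -1.61, PerR and oxidative stress in 14 of 19 with 2 higher (adjusted p = 0.00052, adjusted p = 0.25 with an estimated correlation), and the SOS list in 9 of 16 with 1 higher (adjusted p = 0.0022, adjusted p = 0.19 with an estimated correlation). Motility and chemotaxis rose in 50 of 54 (adjusted p = 1.6e-11, adjusted p = 0.27 with an estimated correlation), mcpC by 2.72 and tlpA by 2.39.

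Arginine, ornithine and histidine catabolism rose in the wild type in 13 of 14 with 1 lower (adjusted p = 3.4e-08, adjusted p = 0.27 with an estimated correlation), SPbeta in 30 of 35 (adjusted p = 1.9e-07, adjusted p = 0.33 with an estimated correlation), bhlB by 4.36 and yomH by 3.22, purine synthesis in 15 of 19 with 1 lower (adjusted p = 3.0e-05, adjusted p = 0.33 with an estimated correlation), pbuO by 4.64, and pyrimidine synthesis in 10 of 10 (adjusted p = 0.00011, adjusted p = 0.27 with an estimated correlation), pyrAA by 5.39. Osmolyte uptake had 17 of 29 higher and 3 lower (adjusted p = 0.044, adjusted p = 0.30 with an estimated correlation), opuCA by 4.13. Ribosomal proteins were higher in 42 of 51 and lower in 1 (adjusted p = 4.8e-05, adjusted p = 0.59 with an estimated correlation), rpmB by 1.68. Antimicrobial peptide genes did not pass (adjusted p = 0.076), with sdpA and sdpB up by 5.48 and 5.24 and sboA at -5.35. A random slide block, with an estimated correlation of 0.154 between arrays of 1 slide, left 3431 features, with putB at 8.32 and treP at -9.04. Adjusted over the list alone, PBSX had 1 member higher and the ribosomal proteins 45, and the other 17 passing lists had the same counts.

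In the tat mutant acetoin and stress genes fell and arginine synthesis genes rose between the sampling points. acoA, acoB, acoC and acoL changed by -11.90 ± 0.27 (log2, SE, n = 3 arrays per group), -10.65, -9.11 and -8.75 from lysis to recovery, the oligo-beta-glucoside genes licC, licH, licA and licB by -8.67, -8.48, -8.39 and -8.37, and the stress genes ydaD, ydaS, ydaE and yflT by -8.34, -8.27, -8.20 and -8.00. carB, carA, argD, argB, argJ, argF and argC rose by 10.75 ± 0.27, 10.51, 10.44, 9.83, 9.48, 9.42 and 9.21, ydzL and ydcO by 9.46 and 9.40, and ydcS at least 135-fold. S172 rose by 8.56, S171 at least 256-fold and S1517 at least 276-fold, and S534, S1481 and S926 changed by -8.64, -6.98 and -6.96. On 0 of 3 arrays of the lower group at least 50% of the probes of acoA, S534, carA, carB, argD, argB, ydzL and ydcO were well above background. On 1 of 3 those of acoB, argJ, ydaD, ydaE, S172, S1481 and S926 were. These values are not exact sizes. Slide and phase cannot be told apart here either, and with a random slide block 4170 features passed, with acoA at -11.94 and carB at 10.73.

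Of 4298 features that passed in the tat mutant, 2069 were higher and 2229 lower, with 1412 and 1544 at least 2-fold. The higher share of 48.1% became 21.5% after normexp correction, 92.7% in the authors' gene-level table, 92.6% in the series matrix and 95.0% on the spike-in scale. Of the lists 22 passed, none with an estimated correlation, and the medians of 10 changed direction on the spike-in scale. Those that kept it included SigB, lower in 64 of 66 with 1 higher (adjusted p = 5.8e-18, adjusted p = 0.13 with an estimated correlation), CssRS, lower in 4 of 4 (adjusted p = 0.0033, adjusted p = 0.38 with an estimated correlation), arginine synthesis, higher in 9 of 9 (adjusted p = 2.0e-07, adjusted p = 0.13 with an estimated correlation), and branched-chain amino acid and CodY targets, higher in 16 of 16 (adjusted p = 1.5e-08, adjusted p = 0.22 with an estimated correlation), dppB by 6.68. Antimicrobial peptide genes were higher in 40 of 51 and lower in 2 (adjusted p = 2.0e-08, adjusted p = 0.38 with an estimated correlation), sdpC by 8.73 and albD by 6.56, and the respiratory chain in 18 of 22 with 3 lower (adjusted p = 0.00082, adjusted p = 0.41 with an estimated correlation), ctaD by 5.10. The Fur list fell in 27 of 27, with feuA at -4.73, but its median turned from -1.87 to 0.95 on the spike-in scale (adjusted p = 3.8e-08, adjusted p = 0.13 with an estimated correlation). Ribosomal proteins, lower in 39 of 51 and higher in 4, turned from -1.50 to 1.31, and their shift to 0.35 after normexp correction (adjusted p = 1.8e-05, adjusted p = 0.44 with an estimated correlation), and glycolysis, lower in 12 of 13, from -2.15 to 0.67 (adjusted p = 7.2e-05, adjusted p = 0.39 with an estimated correlation). The histidine genes hutH and hutM rose by 7.38 and 7.13 within a catabolism list that did not pass (adjusted p = 0.97). The proteases had 1 member lower when adjusted over the list alone, and the other 21 lists had the same counts.

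Whether the effect of losing Tat differed between the phases was tested as the difference of the tat effects, recovery minus lysis. It was -16.28 ± 0.38 (log2, SE, 3 arrays in each of 4 groups) for acoA, -14.74 for acoB, -13.04 for rocA and -11.44 for acoC, and 11.61 ± 0.38 for carB, 11.32 for carA, 10.88 for albF, 10.77 for albG and 10.24 for argD. The fitted difference of pyrB, -11.59, includes a group in which it was not well above background. Those of acoA, carA, carB and argD include at least 1 group with 0 of 3 arrays at 50% of their probes above it, and that of acoB 2 groups with 1 of 3. Their sizes and order are not exact. S171, S683 and S172 were at 9.52, 9.12 and 9.02, and S1460, S534 and S1551 at -11.34, -11.07 and -10.02, with S171, S683, S172 and S534 near background in at least 1 group. In all 3674 features passed, 1504 higher and 2170 lower, with 1078 and 1661 at least 2-fold, around an all-gene median of -0.26. Of the 3674, 923 had tat effects that passed in opposite directions, 597 higher at lysis and lower at recovery and 326 the reverse. The higher share of 40.9% became 16.6% after normexp correction, 55.0% with quantile normalization, 51.7% with array median scaling, 92.9% in the authors' gene-level table, 92.0% in the series matrix and 92.9% on the spike-in scale.

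The list test of that difference passed 20 lists, none with an estimated correlation, and 7 medians changed direction on the spike-in scale. For low-oxygen genes the difference passed above 0 in 19 of 21 (median 5.44, adjusted p = 1.8e-09, adjusted p = 0.27 with an estimated correlation), at 8.51 for cydC and 512-fold for fnr. Their mean shift was -5.74 at lysis and -0.58 at recovery, so the decrease was smaller at recovery and did not become a rise. RNA of these genes had itself fallen in the wild type between the phases. SigB was lower in 61 of 66 and higher in 3 (median -4.34, adjusted p = 1.5e-16, adjusted p = 0.094 with an estimated correlation), ydaS at -9.33 and katE at -8.71. Ribosomal proteins were lower in 47 of 51 (median -2.25, or 0.27 on the spike-in scale, adjusted p = 1.0e-09, adjusted p = 0.36 with an estimated correlation), rpsT at -3.64, and the Pho list in 13 of 18 with 2 higher (median -1.87, or 0.65 on the spike-in scale, adjusted p = 0.0074, adjusted p = 0.36 with an estimated correlation), glpQ at -7.79. Arginine, ornithine and histidine catabolism, with 7 higher and 7 lower, did not pass (adjusted p = 0.58), and rocB was at -10.93. Adjusted over the list alone, 7 of the 20 lists had 1 more called member, low-oxygen genes 20 higher among them. With the slide as a block 2999 features passed, and 2804 within the slides that held both strains. acoA was at -16.77 and -17.20, and carB at 11.16 and 11.08. The SigB shift of -3.85 was -3.91 and -3.92, and the low-oxygen shift of 5.16 was 3.85 and 3.62.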

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

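The test of the difference between the phases was planned, and no test in this part was chosen after the result was seen. In all, 3674 features had a tat effect that differed between recovery and lysis (limma, adjusted p under 0.05). Of 100 splits of the 12 arrays within the phases, 1, the real one, called as many, and the highest other split called 1810. The other splits mix the strains in at least 1 phase, which takes away the tat effect itself there. They cannot show whether equal tat effects in both phases could give this count, so no conclusion on chance is drawn.

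The difference of the tat effects (recovery minus lysis, log2) was 11.61 for carB, 11.32 for carA, 10.88 for albF, 10.77 for albG and 10.24 for argD, and -16.28 for acoA, -14.74 for acoB, -13.04 for rocA, -11.59 for pyrB and -11.44 for acoC. albF and albG were lower in the tat mutant at lysis, at -3.91 and -3.74, and higher at recovery, and acoA, acoB, acoC and rocA went the opposite way. Several of these genes were near background in at least 1 group (acoA, acoB, carA, carB, argD and pyrB), so the sizes are fitted values and not exact.

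Among gene lists the signed difference of the mean shifts, recovery minus lysis, was above 0 for arginine synthesis (9.94), low-oxygen genes (5.16), branched-chain amino acid and CodY targets (3.14), antimicrobial peptides (2.34), the TnrA list (2.21), LiaRS (1.76), the aerobic respiratory chain (1.61), PBSX (1.46), SigW (1.37) and Fur (1.27). It was below 0 for pyrimidine synthesis (-6.93), SigB (-3.85), CcpA-repressed carbon use (-3.08), purine synthesis (-2.95), CssRS (-1.78), ribosomal proteins (-1.77), the biofilm matrix (-1.75), the Pho list (-1.55), the TCA cycle (-1.18) and SPbeta (-1.04). The sign does not give the size of either shift: low-oxygen genes were at -5.74 at lysis and -0.58 at recovery and PBSX at -3.56 and -2.10, while pyrimidine synthesis was at -0.25 and -7.17, purine synthesis at -0.33 and -3.28, ribosomal proteins at -0.35 and -2.12 and the biofilm matrix at -1.18 and -2.93. The camera adjusted p lay between 1.5e-16 and 0.012 for these 20 lists. With an estimated correlation none of the 20 passed, the adjusted p lying between 0.094 and 0.65. Of the 20 medians, 7 changed sign on the spike-in scale: CssRS, the biofilm matrix, SPbeta, the Pho list, ribosomal proteins, the TCA cycle and CcpA-repressed carbon use.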

How the results depend on the processing

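The spike-in scaling, the gene-level table scaled to its own 75th percentile, the fits within slides and the fits without the tat mutant lysis arrays were chosen after the data were seen; the other alternatives were planned. Of the values under the alternatives, 149 counts stayed within 1.5 times the reported count and 7 did not. Of the values of named genes 10351 kept their direction and side of the threshold, 98 reversed, 121 newly passed and 196 no longer passed, and of those of lists 5406, 11, 97 and 184. Many named genes were chosen for large changes in these data, and many alternatives share nearly all arrays. The totals are therefore no measure of robustness. Of the 98 gene reversals, 32 came with spike-in scaling, 28 in the gene-level table, 25 in the series matrix and 12 after normexp correction. The 7 counts were 2284 (tat mutant at recovery), 1634 (S313 mutant), 1857 (phases of the wild type) and 758 (between the mutants) after normexp correction, and within single slides, which leave fewer arrays, 2343 (tat mutant at recovery) and 1353 and 1172 (between the mutants). Leaving out each array in turn gave 3803 to 3949 features for the tat mutant at lysis, 3612 to 3786 at recovery, 3189 to 3369 for the S313 mutant, 3294 to 3656 and 4105 to 4191 between the phases of the wild type and the tat mutant, 3453 to 3846 for the difference of the tat effects and 2127 to 2571 between the mutants. With the replicate as a block the counts were 3994, 3951, 3516, 3593, 4313, 3692 and 2625 in the same order, but correlations of deviations between equally numbered arrays ran from -0.29 to 0.51, so the numbers do not pair the samples. Scan days coincide with slides, so no separate fit was run. Without the tat mutant lysis arrays 3939 features passed for the tat mutant at recovery and 3502 for the S313 mutant. Signal over background limits the 465 features not tested and the genes given as bounds.

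The series matrix, the gene-level table and the spike-in scale keep the low overall signal of the tat mutant lysis arrays. By construction this moves all changes of the tat mutant at lysis down, and its changes between the phases up. The differences of the tat effects, recovery minus lysis, move up for the same reason. For the other reversals the cause was not tested. The values of cotC at lysis and those of tatCY and cotC in the tat mutant compare signals near background and are not changes in RNA. tatAY is deleted in the tat mutant, where its signal was 10.4 at lysis and 8.96 at recovery. Its values that use both tat mutant groups do not measure a change in its RNA there either. No tat mutant array had at least 0.5 of its tatCY probes well above background.

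After normexp correction, the reversed values in the tat mutant at lysis were ykuE 1.91, liaR 0.48, liaS 0.38, liaF 1.11, epsK 1.60, tasA 1.12, the Fur list -1.21, the biofilm list 0.53, the heat shock list -1.25, the TCA list -1.43. After normexp correction, the reversed values in the tat mutant at recovery were phoD 0.030. After normexp correction, the reversed values between the phases of the wild type were prkA 0.11. After normexp correction, the reversed values between the phases of the tat mutant were tatAC -1.11, ykuE -0.59, the ribosomal list 0.35, the TCA list 0.50. After normexp correction, the reversed values in the difference of the tat effects were tatAC -2.06, ykuE -0.70, the PerR list 0.72, the heat shock list 1.04, the TCA list 0.37.

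With quantile normalization, the reversed values between the phases of the wild type were pcp -0.26.

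In the authors' gene-level table, the reversed values in the tat mutant at lysis were phoD -1.70, qcrA -2.41, liaH -0.12, liaI -0.17, liaG -2.59, cssS -0.14, bslA -0.72, odhB -1.49, spoVR -0.17, cotC -1.24, rex -2.40, pcp -0.95, yhbF -2.53, prkA -1.44. In the authors' gene-level table, the reversed values between the phases of the tat mutant were efeB 1.42, rex 2.17, pcp 1.67, yhbF 2.15, prkA 1.58. In the authors' gene-level table, the reversed values in the difference of the tat effects were tatAY 0.46, tatCY 0.70, phoD 0.68, htrB 0.27, cssR 0.42, htrA 0.58, cssS 0.66, pcp 1.62, prkA 2.37.

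In the series matrix, the reversed values in the tat mutant at lysis were S313 -1.51, phoD -1.34, qcrA -2.22, liaG -2.40, bslA -0.53, odhB -1.30, cotC -1.0, rex -2.25, pcp -0.77, yhbF -2.35, prkA -1.25. In the series matrix, the reversed values between the phases of the tat mutant were efeB 1.27, rex 2.05, pcp 1.53, yhbF 2.01, prkA 1.44. In the series matrix, the reversed values in the difference of the tat effects were tatAY 0.52, tatCY 0.51, phoD 0.41, htrB 0.064, cssR 0.22, htrA 0.37, cssS 0.46, pcp 1.43, prkA 2.17.

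On the spike-in scale, the reversed values in the tat mutant at lysis were S313 -1.60, phoD -1.43, qcrA -2.31, liaH -0.019, liaI -0.071, liaG -2.49, cssS -0.043, bslA -0.62, odhB -1.39, spoVR -0.067, cotC -1.10, rex -2.34, pcp -0.86, yhbF -2.44, prkA -1.35. On the spike-in scale, the reversed values between the phases of the tat mutant were tatAY 0.23, tatCY 0.26, efeB 1.71, cotC 0.28, rex 2.49, pcp 1.98, yhbF 2.45, prkA 1.88. On the spike-in scale, the reversed values in the difference of the tat effects were tatAY 0.66, tatCY 0.63, phoD 0.55, htrB 0.20, cssR 0.36, htrA 0.51, cssS 0.59, pcp 1.56, prkA 2.30.

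Among genes detected on all 15 arrays, the reversed values in the tat mutant at lysis were the biofilm list 0.64. Among genes detected on all 15 arrays, the reversed values between the phases of the tat mutant were the low-oxygen list 1.20.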

Other observations

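The tests of hybridisation and of the slide for the low signal, and the test of the SOS list, were chosen after the results were seen.

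The overall signal of the tat mutant lysis arrays lay far below the spike-in level. Weaker hybridisation or scanning would have lowered the spike-in probes too, but their level differed by 0.092 (log2) from that of the wild-type arrays. A slide effect is argued against by the slide that holds both strains, where the tat mutant arrays lay at -2.68 (log2) relative to the wild-type array. What stays open, and was not tested, is whether the labelled RNA of these cultures held less mRNA, as lysing cells may, or differed in quality.

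The tat and S313 mutants shared most of their changes at recovery. The slide of the wild-type arrays is argued against as the whole source, since changes within the slide that holds all 3 strains had a median ratio of 0.97 to those over all slides. Shared wild-type arrays alone gave a covariance of at most 0.029 in 100 simulations, against 2.00 observed. A state common to both mutants, or a difference in growth stage at sampling, may remain, and neither was tested.

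Several genes of ICEBs1 rose in both mutants at recovery: xis by 8.79 in the tat mutant and 5.47 in the S313 mutant, int by 2.82 and 1.40, and rapI by 2.71 and 1.21, while phrI rose by 0.87 and 0.62. immR of the same element, at 2.38 and 0.91, did not pass in the S313 mutant (limma adjusted p = 0.056). ICEBs1 was not among the fixed gene lists and had no list test. An ongoing DNA damage response could raise this element, but the SOS list had a mean change of -0.026 ± 0.20 (SE over members) in the tat mutant and -0.15 ± 0.16 in the S313 mutant, and recA changed by -0.38 and -0.32. A rise through rapI stays a candidate explanation that was not tested, and an earlier, ended damage response stays open.

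For each comparison of 3 against 3 arrays the 10 splits are too few for a share under 0.05. In each, 1 split, the real one, called as many genes. The other splits mix the strains or phases, which puts their difference into the spread. Their low counts were therefore largely fixed in advance, and no conclusion on chance is drawn from them. The real and the highest other counts were 3971 and 1 for the tat mutant at lysis, 3934 and 1 at recovery, 3504 and 0 for the S313 mutant, 3584 and 1 between the phases of the wild type, 4298 and 0 of the tat mutant, and 2610 and 1 between the mutants.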
